A study of Mus musculus with 7 samples.

How the data were processed

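Polyadenylated RNA of sorted mouse lung myeloid cells was sequenced in 7 libraries, from 25 ng of RNA each, with a stranded kit, 15 PCR cycles and paired reads of 58 bp on an Illumina instrument. The deposited values are counts per gene and library, whole numbers that, per the submitters' processing notes, came from a pipeline naming DRAGEN, DESeq2 and the mouse genome build mm10. Versions, the annotation, the strand that was counted and any filter are not given in the sources used here. The count table held 26130 genes, 6880 of them with no count, and 0 sample columns were left unused.

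Libraries were grouped by the labels as untreated Fth1-low (n = 2), LPS Fth1-low (n = 2) and LPS Fth1-high (n = 3). The labels do not state whether replicates were single mice, pools or repeated preparations, so p-values measure only the spread between libraries, which may be partly technical. Female Xist and Y-chromosome Ddx3y were 3.58 and 97.9 CPM in untreated replicate 1 and 274 and 0.186 CPM in replicate 2. They also differed in this way between LPS Fth1-high replicates 2 and 3. For these pairs the values argue against repeated preparations of the same mice, and for the LPS Fth1-low pair the question stays open. Untreated Fth1-high cells were not analysed here. The comparison of LPS Fth1-high with untreated Fth1-low cells therefore mixes treatment and gate, and no test of whether LPS acted differently in the 2 gates was possible.

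Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes passed filterByExpr (13665 tested), libraries were scaled by TMM, and 1 robust quasi-likelihood model of the 3 groups was fitted to all 7 libraries (residual df 4, median prior df 5.38, biological coefficient of variation 0.301). The 3 pairwise differences were tested two-sided, and genes with a Benjamini-Hochberg adjusted p below 0.05 were called. Standard errors are the log2 change over the square root of F. CPM values use TMM-scaled library sizes, and correlations used log2 CPM with a prior count of 2. Gene lists written from general knowledge of monocyte and macrophage biology were tested with camera of limma 3.58.1, with a preset correlation of 0.01 and with an estimated correlation. Each list was also adjusted on its own. Where a group had no count, a fold change is given against a floor of 3 counts over the group, and ratios to 1 to 3 counts carry a 95% interval. Those floors and intervals cover counting error only.

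The model, the filter, the threshold, the lists, the naming rule and most alternatives were chosen before the data were examined. Named genes were the 10 largest rises and falls among called genes with a mean of at least 10 CPM and no overlap between groups, skipping gene models and immune receptor genes. To these were added up to 4 members of each list described by smallest adjusted p, or its 2 most abundant members where none was called, and the ferritin and sort marker genes. Only some genes the rule gives are named. The receptor and complement families of the closing section, and Mmp25, Lrg1, Xist and Ddx3y there, lie outside it and were chosen after their values were seen. List members can sit on several lists: 7 of 19 classical monocyte genes, 5 of 22 macrophage differentiation genes, 7 of 19 lipid-associated genes, 9 of 26 wound repair genes, 3 of 30 iron genes, 4 of 24 NRF2 genes, 3 of 33 inflammatory genes, 3 of 20 hypoxia genes, 2 of 18 glycolysis genes, 1 of 32 lysosome genes, 1 of 17 nonclassical monocyte genes and 1 of 19 dendritic cell genes occur on another list. Gene positions are of GRCm38 (mm10) with GENCODE vM21, 1-based, and 96.2% of gene symbols matched. Of 190 genes under the naming rule, 51 overlap a gene on the opposite strand, among them Ftl1, Ace, Cxcl10, Stab1 and Vcan. Others, among them Serpinb10, F5, Anpep, Abcc1, Ctsd and Trf, overlap a gene on the same strand, which stranded reads do not tell apart. Near-identical copies of ferritin, Ly6c, C1r, Gbp and Ifitm genes may also share reads.

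Depth ranged from 637787 counts in LPS Fth1-low replicate 1 to 27997007 in LPS Fth1-high replicate 3. The other libraries held 16.4 to 43.9 times the counts of the shallowest. In that library 3 counts equal 5.02 CPM, against 0.106 to 0.280 CPM elsewhere. The procedure was tested on simulated data, with 100 genes changed by a log2 value of 1 and 100 by 2 in each comparison. It recovered 32%, 9% and 31% of the smaller changes for LPS Fth1-high against LPS Fth1-low, LPS Fth1-low against untreated, and LPS Fth1-high against untreated, and 73%, 77% and 84% of the larger. Of the genes called there, 12.5%, 5.49% and 7.26% were unchanged.

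Alternatives were other scalings, the DESeq2 1.42.0 Wald test, limma-voom, other filters, fits of only 2 groups, each library left out in turn, the replicate number as a block, a minimum fold change, and mitochondrial, ribosomal protein and model genes left out. Ribosomal RNA genes left out, voom with sample quality weights and libraries thinned to equal depth were added after the data were seen. Equal depth here means equal total counts with ribosomal RNA included, so depth over the other genes still differed. When a library of a group of 2 is left out, the lone library is assumed to vary like those of the other groups. With groups of 2, 2 and 3, no test of other splits of the samples was informative. Reads, flow cytometry and protein levels were not analysed here.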

Results

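RNA was sequenced from myeloid cells sorted from the lungs of mice that carried a fluorescent reporter of Fth1 and a GFP reporter of Lyz2. Fth1 encodes the heavy chain of ferritin, the cytosolic iron store, and Lyz2 encodes lysozyme, a marker of myeloid cells. The sort took GFP-positive cells with CD11b and Ly6C and without Ly6G, a gate for monocytes and the macrophages they give rise to that leaves out neutrophils, and divided them by low or high Fth1 reporter signal. The mice were untreated or had received 20 µg of lipopolysaccharide (LPS, a bacterial cell wall component) in 50 µl into the trachea 3 days before. The 7 libraries comprised 2 of untreated Fth1-low cells, 2 of LPS Fth1-low cells and 3 of LPS Fth1-high cells. Total gene counts were 22995442 and 10459703 in the untreated libraries, 637787 and 19001523 in the LPS Fth1-low libraries, and 15285553, 25270965 and 27997007 in the LPS Fth1-high libraries. LPS Fth1-low replicate 1 was thus the shallowest, with 12292 genes detected, and 1 count there stood for 1.67 CPM. Ribosomal RNA took 19.4% of its counts (95% Wilson interval 19.3% to 19.5%), against 1.86% (1.86% to 1.87%) in replicate 2 of its group and 8.42% (8.40% to 8.43%) in LPS Fth1-high replicate 1. Its log2 CPM correlated with its partner at 0.863 (Pearson, across genes, which are not independent replicates), where the untreated pair had 0.964 and the LPS Fth1-high pairs 0.960 to 0.980. Unless another error is named, values below are CPM as group mean ± SD with n = 2, 2 and 3 for the groups in the order above, and log2 changes ± SE with Benjamini-Hochberg adjusted p of edgeR's quasi-likelihood test.

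Ferritin transcripts came first, because the Fth1 gate should separate libraries by Fth1 itself. Fth1 (chromosome 19, 9980598 to 9985098 in mm10, plus strand) stood at 1729 ± 81.1 CPM in untreated Fth1-low, 3898 ± 1312 in LPS Fth1-low and 18234 ± 4342 in LPS Fth1-high cells. LPS Fth1-high exceeded LPS Fth1-low by 2.22 ± 0.35 (adjusted p = 0.0047), a 4.67-fold difference in the gene used for the gate and so no independent finding. Between the Fth1-low groups the difference of 1.17 ± 0.35 was not called (adjusted p = 0.143), although the DESeq2 Wald test called it (adjusted p = 0.0013), as did edgeR on libraries thinned to equal depth (adjusted p = 0.021). Ftl1, the ferritin light chain, was not a gate gene. It was 1371 ± 297 CPM in LPS Fth1-high and 583 ± 147 in LPS Fth1-low cells, higher by 1.24 ± 0.28 (adjusted p = 0.024). That call was lost without LPS Fth1-low replicate 2 (adjusted p = 0.098), LPS Fth1-high replicate 2 (0.073) or replicate 3 (0.086). Of the sort's other markers, Lyz2 differed by -0.03 ± 0.29 between the LPS gates (adjusted p = 0.971), and Itgam, which encodes CD11b, by 0.90 ± 0.27 (adjusted p = 0.081). Ly6c2 differed by 1.03 ± 0.32 (adjusted p = 0.093), and Ly6g had at most 2 counts in any library. Reads of Fth1, Ly6c1 and Ly6c2 may be divided among similar genes, so their levels are uncertain. The count table held 7 genes with ferritin heavy chain-like symbols, whose sequence identity to Fth1 was not tested.

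**Figure D1:**
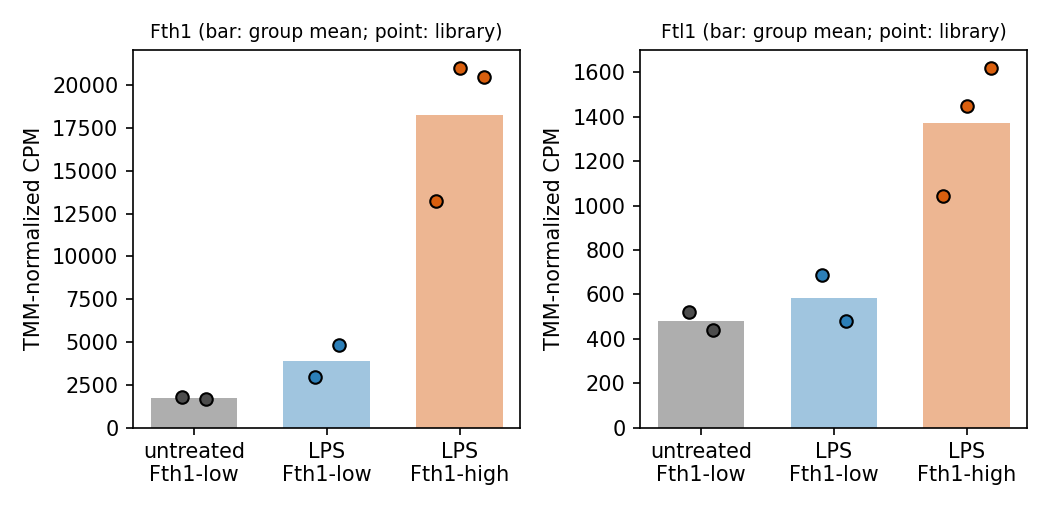
Fth1 (left) and Ftl1 (right) in TMM-normalized CPM on linear axes from 0, with bars for group means and points for single libraries of untreated Fth1-low (n = 2), LPS Fth1-low (n = 2) and LPS Fth1-high cells (n = 3). Fth1 averaged 1729, 3898 and 18234 CPM in that order, and Ftl1 averaged 481, 583 and 1371 CPM.

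The first comparison asked how Fth1-high cells differed from Fth1-low cells after LPS. The Fth1-high cells held far more transcript of Gpnmb, a transmembrane glycoprotein of lysosome-rich macrophages, at 829 ± 284 against 18.0 ± 13.6 CPM (log2 difference 5.22 ± 0.48, adjusted p = 3.3e-04). Arg1 (chromosome 10, 24915221 to 24927484 in mm10, minus strand), the arginine-degrading enzyme of tissue macrophages, was 197 ± 80.1 against 5.88 ± 5.94 CPM (4.51 ± 0.50, adjusted p = 9.0e-04). It was the only gene called higher of 15 tested from the list of alternative activation genes, where 2 were lower (2 higher and 4 lower adjusted over the list alone). That list had a median of -0.38 and camera adjusted p = 0.71, and its median was 0.87 without LPS Fth1-low replicate 2. Other genes went the other way. Serpinb10, an intracellular serine protease inhibitor of myeloid progenitors and monocytes, averaged 0.759 CPM in Fth1-high and 129 CPM in Fth1-low cells (-7.42 ± 0.69, adjusted p = 7.0e-04), a 171-fold difference. The annotation used for positions lists Serpinb10 as a polymorphic pseudogene, and it overlaps Serpinb2 on the same strand. Ifitm6, a member of the interferon-induced transmembrane family that marks classical monocytes, was 2.00 ± 0.583 against 242 ± 74.7 CPM, 121-fold lower (adjusted p = 5.6e-05).

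Of 13665 genes tested, 503 were higher and 625 lower in Fth1-high than in Fth1-low cells after LPS. The groups' libraries did not overlap for 1112 of these 1128 genes, where chance gives 20.0% and all tested genes gave 41.3%. Among the largest rises were C1s1, a complement protease (4.12 ± 0.52, adjusted p = 0.0019), Fblim1, a filamin-binding adaptor of cell junctions (4.13 ± 0.39, 4.0e-04), and the noncoding RNA Mirt2 (4.05 ± 0.44, 7.1e-04). The largest falls took in F5, coagulation factor V (-6.48 ± 0.45, adjusted p = 1.2e-04), Flt3, the receptor tyrosine kinase of dendritic cell progenitors (-5.43 ± 0.40, 1.4e-04), and Cd177, a surface glycoprotein of neutrophils and some monocytes (-4.94 ± 0.33, 9.5e-05). Cd300lg, a CD300-family adhesion receptor, fell by 4.95 on the log2 scale (adjusted p = 5.6e-05). Every one of these genes kept its call when any single library was left out, but the sizes moved. Without LPS Fth1-low replicate 2 the differences became 6.64 for Gpnmb, 6.88 for Arg1, 5.50 for Fblim1, 5.23 for C1s1 and -4.25 for Flt3. In that fit LPS Fth1-low replicate 1 stood alone, with C1s1 at 5.02 CPM, the value of 3 counts there. Arg1 was near this floor in that library as well, so both differences are uncertain in that fit. Without LPS Fth1-high replicate 3 the differences became -8.30 for Serpinb10 and -7.14 for F5. The counts were 306 higher without LPS Fth1-low replicate 1, 379 lower without its replicate 2, 263 higher and 395 lower without LPS Fth1-high replicate 2, and 291 higher and 390 lower without LPS Fth1-high replicate 3.

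Many genes of the macrophage differentiation, lipid-associated macrophage and lysosome lists were higher in the Fth1-high cells, and few of the interstitial and alveolar macrophage lists were. In the list of macrophage differentiation genes, 10 of 22 rose and none fell (14 and 0 adjusted over the list alone), with a median difference of 1.02. C3ar1, the receptor for complement fragment C3a, was 509 ± 14.4 against 82.4 ± 71.5 CPM (adjusted p = 0.0096) and C1qc, a chain of complement C1q, was 547 ± 134 against 128 ± 76.2 CPM (adjusted p = 0.011). The lipid-associated macrophage list had 10 of 19 higher and 0 lower (12 and 3 over the list alone), with a median of 1.69. Besides Gpnmb it held Abca1, the cholesterol exporter, at 651 ± 88.8 against 57.0 ± 33.3 CPM (3.39 ± 0.35, adjusted p = 5.6e-04). Stab1, a scavenger receptor on the list of interstitial macrophage markers, was 5.79-fold higher at 599.6 ± 88.0 CPM (adjusted p = 5.6e-04). Of the 14 genes tested from that list, 1 rose and 1 fell (1 and 3 over the list alone), with a median of -0.83 and camera adjusted p = 0.58. The median was 2.78 without LPS Fth1-low replicate 2. The 1 that fell was Lyve1, a hyaluronan receptor (-2.03 ± 0.47, adjusted p = 0.028), whose call was lost without untreated replicate 1 or 2, LPS Fth1-low replicate 2 (when it differed by -1.20), or LPS Fth1-high replicate 1 or 2, and 2 genes fell without LPS Fth1-low replicate 1. The alveolar macrophage list had 2 of 18 higher and 0 lower (2 and 4 over the list alone, camera adjusted p = 0.63), with a median of -0.07, a mean of 0.17 and camera pointing lower. It had 0 higher without LPS Fth1-low replicate 2, 2 lower without LPS Fth1-high replicate 1, 1 higher and 1 lower without replicate 2 or 3 of that group, and 1 higher without any of the other 3 libraries. Its median was 0.24 without LPS Fth1-low replicate 1 or untreated replicate 2, and 0.32 without LPS Fth1-high replicate 2. The lysosome list had 11 of 32 higher and none lower (21 and 0 over the list alone), among them Tpp1, a lysosomal peptidase (1.45 ± 0.20, adjusted p = 0.0024), and Npc1, which exports cholesterol from lysosomes (1.77 ± 0.29, 0.0062). Camera with a preset correlation gave adjusted p = 8.7e-10, 1.4e-09 and 2.2e-11 for the macrophage differentiation, lipid-associated and lysosome lists, and adjusted p = 0.25, 0.28 and 0.43 with an estimated correlation. The counts of genes that rose, in the same order, were 4, 5 and 4 without LPS Fth1-low replicate 1. The macrophage and lysosome lists had 5 each without LPS Fth1-high replicate 2, 5 each without its replicate 3 and 6 each without untreated replicate 2, and the lysosome list had 6 without untreated replicate 1 and 18 without LPS Fth1-low replicate 2. In that last fit C3ar1, C1qc, Abca1, Npc1 and Gpnmb differed by 4.01, 2.90, 4.29, 2.48 and 6.64. The outlying LPS Fth1-low replicate 1, with its ribosomal RNA share of 19.4%, had the lowest lysosome sum of all libraries at 17334 CPM, against 28261 in replicate 2.

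Most glycolysis genes and some genes of iron and oxidant handling were also higher. In the iron handling list 7 of 29 genes rose, 1 fell and 21 were not called (9 higher and 5 lower adjusted over the list alone), with a median of 0.30. Fth1, whose reporter set the gate, is among the genes that rose here and in the NRF2 list below. The list values were not computed without it. Hmox1, the heme oxygenase that frees iron from heme, was 553 ± 95.2 against 113 ± 20.0 CPM (2.27 ± 0.24, adjusted p = 7.0e-04), and Slc25a37, the mitochondrial iron importer mitoferrin, was 3.51-fold higher (adjusted p = 8.2e-04). The list of NRF2 targets, genes induced by oxidative stress that share Fth1, Ftl1, Hmox1 and Slc7a11 with other lists, had 9 of 23 higher and 0 lower (11 and 2 over the list alone). It included Abcc1, a glutathione-conjugate exporter (1.66 ± 0.24, adjusted p = 0.0029). Glycolysis had 12 of 18 genes higher and 0 lower (16 and 0 over the list alone) with a median of 1.05, including Pfkl, a phosphofructokinase (2.14 ± 0.26, adjusted p = 0.0013), Tpi1 (744 ± 63.4 against 204 ± 63.4 CPM, 0.0030) and Pgam1 (1.54 ± 0.22, 0.0030). The hypoxia response list had 7 of 17 higher and 2 lower (10 and 2 over the list alone). Bnip3, a mitophagy receptor, rose by 1.75 ± 0.23 (adjusted p = 0.0019), and Ndrg1, a stress-responsive gene, fell by 2.01 (adjusted p = 6.0e-04). Adjusted p by camera for the iron, NRF2, glycolysis and hypoxia lists was 0.0057, 9.1e-05, 1.5e-12 and 7.1e-04 with the preset correlation, and adjusted p = 0.43, 0.13, 0.081 and 0.25 with an estimated correlation. Without LPS Fth1-low replicate 1 the iron list had 5 higher, 3 lower and a median of 0.05, and glycolysis had 5 higher, and without its replicate 2 NRF2 had 5 higher and hypoxia 4 higher and 1 lower. Leaving out LPS Fth1-high replicate 2 gave 4 higher and 0 lower for iron, 5 higher and 1 lower for NRF2 and 5 higher for glycolysis. Replicate 3 of that group left out gave 5 higher and 0 lower for iron and 7 higher for glycolysis, and replicate 1 left out gave 0 lower for iron and 4 higher for hypoxia.

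Many marker genes of circulating monocytes and some of dendritic cells were lower in the Fth1-high cells. Of the classical monocyte list, 10 of 19 genes fell, 1 rose and 8 were not called (11 lower and 2 higher adjusted over the list alone), with a median of -1.13. Vcan, the matrix proteoglycan versican, was 19.7 ± 5.83 against 406 ± 27.7 CPM (-4.37 ± 0.29, adjusted p = 9.5e-05). Clec4d, a C-type lectin pathogen receptor, was the member that rose (599 ± 174 against 119 ± 36.1 CPM, adjusted p = 0.0027). Ly6c2, a sort marker that is also on this list, was not called but lay higher in the Fth1-high cells. It was 1393 and 847 CPM in the LPS Fth1-low libraries and 1981, 2980 and 1854 CPM in the LPS Fth1-high libraries. Of the nonclassical monocyte list, 11 of 17 fell and 1 rose (13 and 1 over the list alone), with a median of -1.46. Ace, angiotensin-converting enzyme, averaged 19.4 against 437 CPM (-4.50 ± 0.63, adjusted p = 0.0043), Treml4, a receptor of nonclassical monocytes, was 14.5 ± 2.33 against 129 ± 28.2 CPM (adjusted p = 1.2e-04), and Nr4a1, the nuclear receptor needed for these cells, was 669 ± 91.8 against 1847 ± 9.34 CPM (adjusted p = 0.0037). Apoc2, an apolipoprotein, was the member that rose (1.85 ± 0.27, adjusted p = 0.0035). In the dendritic cell list 7 of 19 fell, 1 rose and 11 were not called (13 lower and 1 higher over the list alone), with a median of -1.80, and Clec10a, a galactose-binding lectin, was at 4.99 ± 0.309 against 20.7 ± 0.850 CPM (adjusted p = 4.9e-04). Camera's adjusted p was 9.4e-17 for classical, 2.9e-16 for nonclassical and 5.8e-11 for dendritic cell genes, and adjusted p = 0.057, 0.13 and 0.16 with an estimated correlation. Leaving out LPS Fth1-low replicate 2 gave 7 lower for the nonclassical list, and 3 lower and 0 higher for the dendritic list. The 1 rise in the dendritic list was also lost without LPS Fth1-low replicate 1 or LPS Fth1-high replicate 3.

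**Figure D2:**
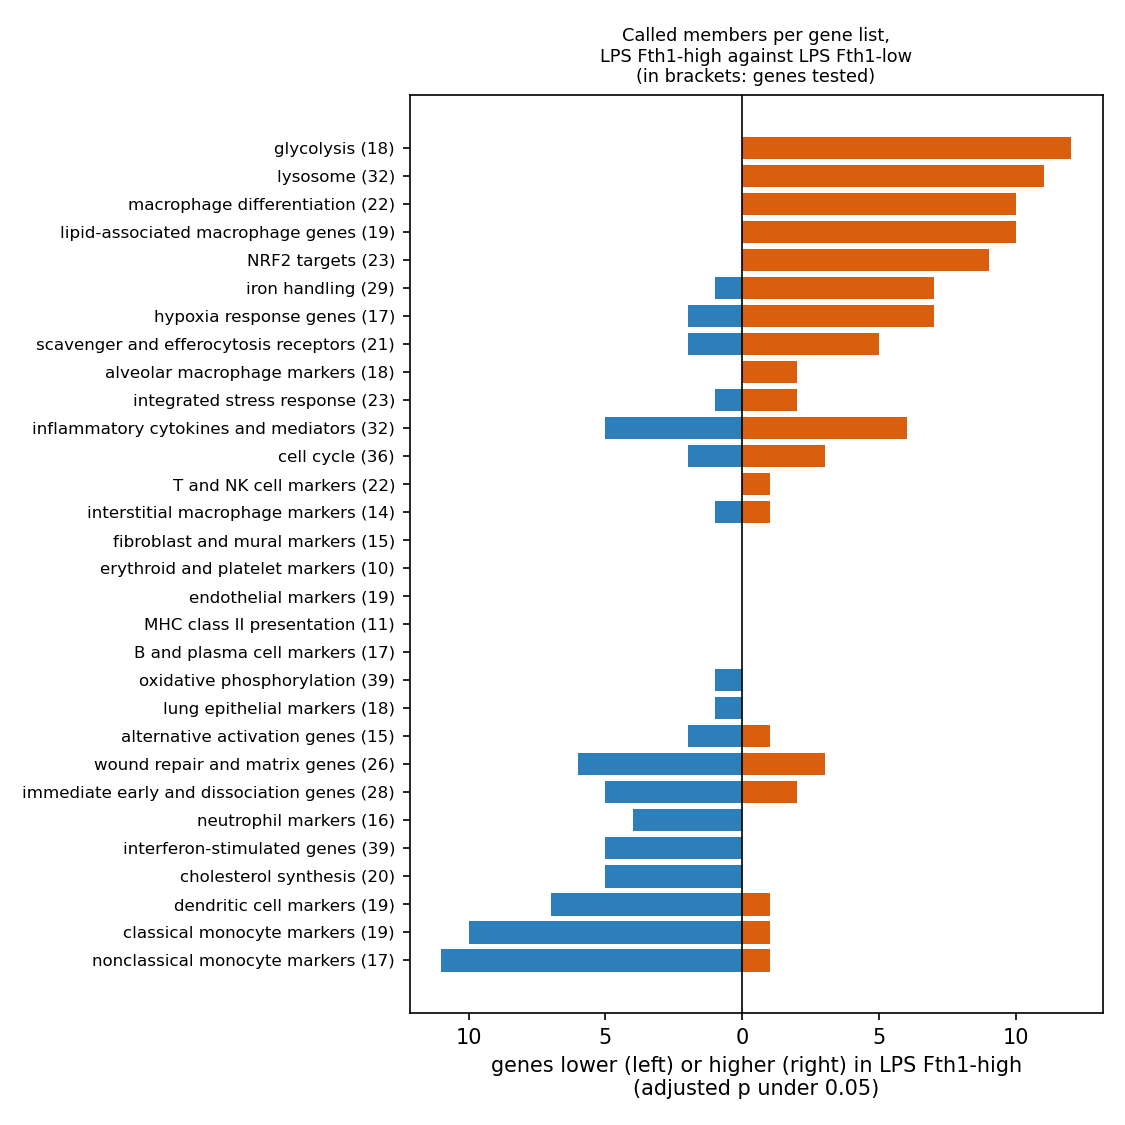
Number of genes per list called higher (right bars) or lower (left bars) in LPS Fth1-high (n = 3) than in LPS Fth1-low cells (n = 2) by edgeR, with the number of genes tested in brackets. Glycolysis had 12 of 18 higher and 0 lower, and nonclassical monocyte markers had 1 of 17 higher and 11 lower.

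Most inflammatory genes were not called between the 2 gates. Of 32 cytokines and mediators tested, 6 were higher, 5 lower and 21 not called in Fth1-high cells (11 higher and 8 lower adjusted over the list alone), and camera gave adjusted p = 0.70. Il12b, the shared subunit of interleukin-12 and interleukin-23, was 5.41 ± 1.30 against 55.3 ± 26.1 CPM (-3.44 ± 0.33, adjusted p = 4.3e-04). Ccl4, a chemokine for T cells and monocytes, was 2.56-fold lower (adjusted p = 0.0047), whereas Cxcl16, a transmembrane chemokine, was 2.47-fold higher (adjusted p = 0.011). The interferon-stimulated list had 5 of 39 lower and 0 higher (6 and 0 over the list alone, camera adjusted p = 0.076), with Cxcl10, an interferon-induced chemokine, at 340.5 ± 81.9 against 882 ± 62.3 CPM (adjusted p = 0.0071). Cholesterol synthesis had 5 of 20 lower and 0 higher (7 and 0 over the list alone, camera adjusted p = 0.0014, adjusted p = 0.72 with an estimated correlation). The wound repair and matrix list had 3 of 26 higher and 6 lower (5 and 7 over the list alone, camera adjusted p = 0.21), with a median of -0.18. Mmp14, a membrane-bound collagenase, was among those that rose, at 1206 ± 109.8 against 380.4 ± 114 CPM (adjusted p = 0.0038). The wound list had 1 higher, 4 lower and a median of 0.08 without LPS Fth1-low replicate 1, and 2 higher, 3 lower and a median of 0.48 without its replicate 2. Without LPS Fth1-low replicate 1 the inflammatory list had 1 higher and 4 lower, interferon genes 2 lower and cholesterol synthesis 3 lower. Without its replicate 2 these were 4 and 2, 2 lower and 1 lower, and Il12b differed by -2.76. The LPS Fth1-high replicates 1, 2 and 3 left out in turn gave 6 and 3, 1 and 3, and 3 and 5 inflammatory genes, 3, 2 and 2 interferon genes, and 2, 3 and 2 cholesterol genes.

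Markers of cells outside the gate were measured beside these groups. The lung epithelial list summed to 472 and 758 CPM in the LPS Fth1-low libraries and to 197, 223 and 279.5 CPM in the LPS Fth1-high libraries. Of that list, 1 of 18 genes fell, Napsa, an aspartic protease of alveolar epithelium that stood at 404 ± 90.7 CPM in Fth1-low and 90.6 ± 13.1 CPM in Fth1-high cells (adjusted p = 5.6e-04). Napsa thus made up much of these sums, so they are no measure of the list as a whole. Which cells held its transcript was not tested. The list's median log2 CPM was 0.84 and 2.33 in the LPS Fth1-low libraries and 1.16, 0.04 and 1.92 in the LPS Fth1-high libraries. Neutrophil markers, 5 of whose 22 members other lists hold, had 4 of 16 tested genes lower and 0 higher in Fth1-high cells (6 and 0 adjusted over the list alone, camera adjusted p = 6.4e-06, adjusted p = 0.25 with an estimated correlation). Il1r2, the decoy receptor of interleukin-1, was 10.6 ± 3.06 against 56.5 ± 4.19 CPM (adjusted p = 5.7e-04), and the list had 2 lower without LPS Fth1-low replicate 2. T and NK cell markers summed to 156 and 67.2 CPM in the LPS Fth1-low and 70.7, 51.4 and 71.3 CPM in the LPS Fth1-high libraries. Their median was -1.43 (camera adjusted p = 0.0057, adjusted p = 0.72 with an estimated correlation), and camera passed neither without LPS Fth1-low replicate 1 (median -0.84, adjusted p = 0.093) nor with a stricter filter on low counts (0.104). Against that direction, 1 of the 22 genes was called higher and 0 lower (0 and 0 over the list alone), Il7r, the interleukin-7 receptor chain (2.14 ± 0.53, adjusted p = 0.041). Its call was lost without either LPS Fth1-low replicate or without LPS Fth1-high replicate 2 or 3, and it differed by 4.32 without LPS Fth1-low replicate 2.

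The next comparison was LPS Fth1-low against untreated Fth1-low cells, the difference with LPS within the low gate. The sort came after the treatment, so these groups need not hold the same kinds of cells. After LPS the Fth1-low cells held Nos2, the inducible nitric oxide synthase, at 481 ± 31.6 against 0.525 ± 0.0827 CPM (9.78 ± 0.51, adjusted p = 2.2e-05). Acod1, which makes the antimicrobial metabolite itaconate, rose from 1.41 ± 0.0124 to 847 ± 352 CPM (adjusted p = 2.5e-05). Cxcl10 rose from 34.8 ± 1.71 to 882 ± 62.3 CPM (4.66 ± 0.30, adjusted p = 5.2e-05). Il12b had 1 count in the untreated libraries, in replicate 1, and 1456 after LPS, a ratio of 2524 with a 95% counting interval of 452 to 99755. Inhba, a subunit of activin, had no count in untreated libraries and was at least 483-fold higher after LPS, against a floor of 3 counts over the untreated group. Spn, the sialoglycoprotein CD43 of nonclassical monocytes, fell from 799 ± 30.6 to 217 ± 79.2 CPM (adjusted p = 0.0052).

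In this comparison 409 genes rose and 86 fell. Libraries did not overlap for 39.5% of tested genes, where chance gives 33.3%. The inflammatory list had 24 of 32 genes higher and 0 lower (28 and 0 adjusted over the list alone, median 3.10), including Cxcl16 (5.04 ± 0.30, adjusted p = 4.0e-05) and Cxcl9, an interferon-gamma-induced chemokine (11.7 ± 6.65 to 1068 ± 17.1 CPM, 9.5e-05). Interferon-stimulated genes had 12 of 39 higher and 0 lower (17 and 0 over the list alone), with the guanylate-binding proteins Gbp2 (3.77 ± 0.30, adjusted p = 1.7e-04) and Gbp5 (4.16 ± 0.33, 1.7e-04). The wound repair and matrix list had 7 of 26 higher and 0 lower (8 and 2 over the list alone). Mmp14 rose from 7.09 ± 0.275 to 380.4 ± 114 CPM (adjusted p = 2.5e-05), Plau, the urokinase protease, from 6.67 ± 0.593 to 49.4 ± 8.24 CPM (2.1e-04), and Vcan from 67.6 ± 19.0 to 406 ± 27.7 CPM (0.0018). Camera gave adjusted p = 9.3e-78, 9.1e-19 and 2.0e-07 for the inflammatory, interferon and wound lists, and adjusted p = 0.093, 0.44 and 0.22 with an estimated correlation. Without untreated replicate 1 those lists had 14, 7 and 3 higher, and the wound list had 3 higher without untreated replicate 2. Over all genes, the counts were 179 higher and 18 lower without untreated replicate 1, 203 and 11 without untreated replicate 2, 22 lower without LPS Fth1-low replicate 1 and 249 lower without its replicate 2. Cxcl9 differed by 7.27 without untreated replicate 2, and the other genes named kept their call with any 1 library left out.

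Some macrophage genes rose with LPS in the low gate too, and some nonclassical monocyte genes fell, though most of either list was not called. In the macrophage differentiation list 6 of 22 rose, 0 fell and 16 were not called (8 higher and 0 lower adjusted over the list alone). The C1q chains moved most, C1qa by 6.77 ± 0.63 (adjusted p = 4.7e-04), C1qb by 5.79 ± 0.50 (2.1e-04) and C1qc by 5.71 ± 0.49 (2.1e-04), with 5.66, 4.81 and 4.83 when LPS Fth1-low replicate 2 was left out, a fit in which the list had 4 higher and 1 lower. Stab1 rose 11.9-fold to 104 ± 6.50 CPM (adjusted p = 1.7e-04), and Slc7a11, the cystine importer, rose by 4.14 ± 0.41 (adjusted p = 5.5e-04). Hk3, a myeloid hexokinase, rose 3.80-fold (adjusted p = 0.0024). In the nonclassical list 6 of 17 fell, 1 rose and 10 were not called (12 lower and 1 higher over the list alone), with Hes1, a Notch target, falling from 63.4 ± 3.10 to 12.6 ± 3.63 CPM (adjusted p = 0.0020). Cd209a, a C-type lectin of dendritic cells and monocytes, fell by 3.67 on the log2 scale (adjusted p = 0.0012). The lysosome list had a median of -0.05 and a mean of 0.02, and camera, which put the list lower, gave adjusted p = 0.60. For the macrophage and nonclassical lists camera gave adjusted p = 8.7e-07 and 2.5e-11, and adjusted p = 0.44 and 0.16 with an estimated correlation. The nonclassical list had 2 lower and 0 higher without either untreated replicate and 3 lower and 0 higher without LPS Fth1-low replicate 1. Its 1 rise was also lost without LPS Fth1-low replicate 2 or LPS Fth1-high replicate 2.

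Markers of other cell types were summed in each of these libraries as well. Lung epithelial markers summed to 1759 and 721 CPM in the untreated libraries, with Sftpc, the surfactant protein of alveolar type 2 cells, at 248 ± 348 CPM, and to 472 and 758 CPM after LPS. The list's median log2 CPM was 4.14 and -1.04 in untreated replicates 1 and 2, so only part of the list carried the sum in replicate 2. Endothelial markers summed to 878 and 282 CPM untreated, 512 and 329 CPM in LPS Fth1-low, and 430.0, 187 and 338 CPM in LPS Fth1-high libraries. Erythroid and platelet markers summed to 24.0 and 61.6 CPM untreated, 13.4 and 14.5 CPM in LPS Fth1-low, and 11.5, 12.7 and 17.1 CPM in LPS Fth1-high libraries. Fibroblast markers were highest in LPS Fth1-low replicate 1 at 187.5 CPM, against 59.7 in replicate 2. B cell markers summed to 491 and 367 CPM untreated, 455 and 176 in LPS Fth1-low, and 192, 34.3 and 136 CPM in LPS Fth1-high libraries. Neutrophil markers summed to 825 and 757 CPM untreated and 931 and 1121 CPM in LPS Fth1-low libraries, and 4 of the 16 tested genes rose with LPS (5 and 1 adjusted over the list alone). That count was 1, 0, 2 and 0 without untreated replicate 1, untreated replicate 2, LPS Fth1-low replicate 1 and LPS Fth1-low replicate 2. The sort had removed cells with Ly6G, the surface marker of neutrophils.

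The last comparison set LPS Fth1-high cells against untreated Fth1-low cells, which differed in both the treatment and the gate. Anpep, aminopeptidase N, rose from 4.52 ± 0.204 to 1407 ± 249 CPM (8.29 ± 0.35, adjusted p = 3.4e-06), and Slc7a2, the arginine importer, from 2.24 ± 0.662 to 1211 ± 229 CPM (adjusted p = 6.6e-06). Nos2 rose to 1195 ± 408 CPM (11.09 ± 0.53, adjusted p = 3.4e-06) and Gpnmb by 7.64 ± 0.52 (adjusted p = 1.2e-05). Ace fell from 2196 to 19.4 CPM (-6.83 ± 0.69, adjusted p = 2.3e-04) and Ifitm6 from 408 ± 113 to 2.00 ± 0.583 CPM (adjusted p = 3.4e-06). Inhba was at least 1685-fold higher against a floor of 3 counts over the untreated group.

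Here 1690 genes rose and 1625 fell, with 58.1% of tested genes not overlapping where chance gives 20.0%. Macrophage differentiation had 16 of 22 higher and 1 lower (16 and 1 adjusted over the list alone), with C1qc up by 7.74 ± 0.51 (adjusted p = 1.0e-05). Glycolysis had 15 of 18 higher and 0 lower (17 and 0 over the list alone), with Pfkl at 378 ± 21.4 against 50.2 ± 3.07 CPM (5.8e-05). The lysosome list had 15 of 32 higher and 1 lower (18 and 1 over the list alone), among them Ctsd, the aspartic protease cathepsin D (4755 ± 1449.8 against 241 ± 85.0 CPM, 4.4e-04). Class II antigen presentation had 7 of 11 higher and 0 lower (7 and 0 over the list alone), with H2-Eb1 at 2332 ± 635 against 480.0 ± 49.9 CPM (7.7e-04) and H2-Ab1 at 3774 ± 923 against 866 ± 104 CPM (0.0014). Between the LPS gates, by contrast, 0 of these 11 genes were called (3 higher and 0 lower over the list alone), with a median of 0.14 and camera adjusted p = 0.20. Against untreated cells, 14 of 17 genes of the nonclassical list fell and 2 rose (14 and 2 over the list alone). Treml4 fell from 349 ± 31.5 CPM (adjusted p = 3.4e-06), Spn from 799 ± 30.6 to 42.6 ± 4.08 CPM (6.9e-06), and Nr4a1 from 3564 ± 101 CPM (6.1e-05). In cholesterol synthesis 14 of 20 fell and 0 rose (14 and 0 over the list alone), with the isomerase Idi1 at 5.75 ± 0.448 against 70.6 ± 31.8 CPM (2.4e-05) and the demethylase Cyp51 at 15.9 ± 3.76 against 126 ± 39.8 CPM (1.3e-04). Iron handling had 13 of 29 higher and 5 lower (14 and 6 over the list alone), with Slc25a37 7.75-fold higher (1.4e-05) and Trf, the iron carrier transferrin, falling from 423 ± 63.5 to 70.5 ± 21.2 CPM (4.8e-04).

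Camera for the macrophage, glycolysis, lysosome, class II, nonclassical, cholesterol and iron lists in this last comparison gave adjusted p = 3.8e-10, 2.2e-11, 9.1e-05, 0.0080, 1.6e-19, 3.2e-09 and 0.020. With an estimated correlation the values were adjusted p = 0.39, 0.19, 0.70, 0.46, 0.18, 0.42 and 0.46. Without untreated replicate 1 the counts were 955 higher and 963 lower over all genes, 11 and 0 for the macrophage list, 9 and 0 for the lysosome list and 4 higher for class II. Without untreated replicate 2 they were 973 and 948, 10 and 0, 7 and 0, and 3 higher, and cholesterol synthesis had 9 lower and iron handling 8 higher and 4 lower. Leaving out LPS Fth1-high replicate 2 gave 1055 lower over all genes. The 1 macrophage gene that fell, Mrc1 (12.5 ± 6.52 against 35.5 ± 8.05 CPM, adjusted p = 0.047), lost its call in that fit (adjusted p = 0.139), without LPS Fth1-high replicate 1 (0.099) and without untreated replicate 1 (0.098) or 2 (0.227). Without LPS Fth1-high replicate 1 class II had 4 higher, and without replicate 3 class II had 4 higher and lysosome 10 higher and 0 lower.

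Markers of other cell types were set beside this comparison too. The erythroid and platelet list had 5 of 10 lower and 0 higher (7 and 2 adjusted over the list alone), with a median of -3.02 and camera adjusted p = 0.16. It had 2 lower without untreated replicate 2, 1 without LPS Fth1-high replicate 1, and 3 without replicate 2 or 3 of that group or either LPS Fth1-low replicate. T and NK cell markers summed to 133 and 59.7 CPM untreated and had a median of -1.61 (camera adjusted p = 0.026, adjusted p = 0.70 with an estimated correlation), with 1 of 22 higher, Il7r, and 2 lower, Nkg7 and Klrb1c of cytotoxic cells (1 and 0 over the list alone). The camera call was lost without untreated replicate 1 (median -0.80, adjusted p = 0.24) and with a stricter filter on low counts (0.25), and 0 genes were lower without untreated replicate 1 or LPS Fth1-high replicate 2, 1 without LPS Fth1-low replicate 1 and 6 without LPS Fth1-high replicate 1. The lung epithelial list had 2 of 18 lower and 0 higher (1 and 0 over the list alone), among them Napsa (-2.85 ± 0.22, adjusted p = 2.5e-05), with a median of -2.13 and camera adjusted p = 0.12. Without untreated replicate 1 the median was 1.95, and 7 genes were lower without untreated replicate 2 and 1 without any other library. The B cell list had 2 of 17 lower and 0 higher (1 and 0 over the list alone, camera adjusted p = 0.12), with 0 lower without untreated replicate 1 and 1 without untreated replicate 2, either LPS Fth1-low replicate or LPS Fth1-high replicate 3.

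**Figure D3:**
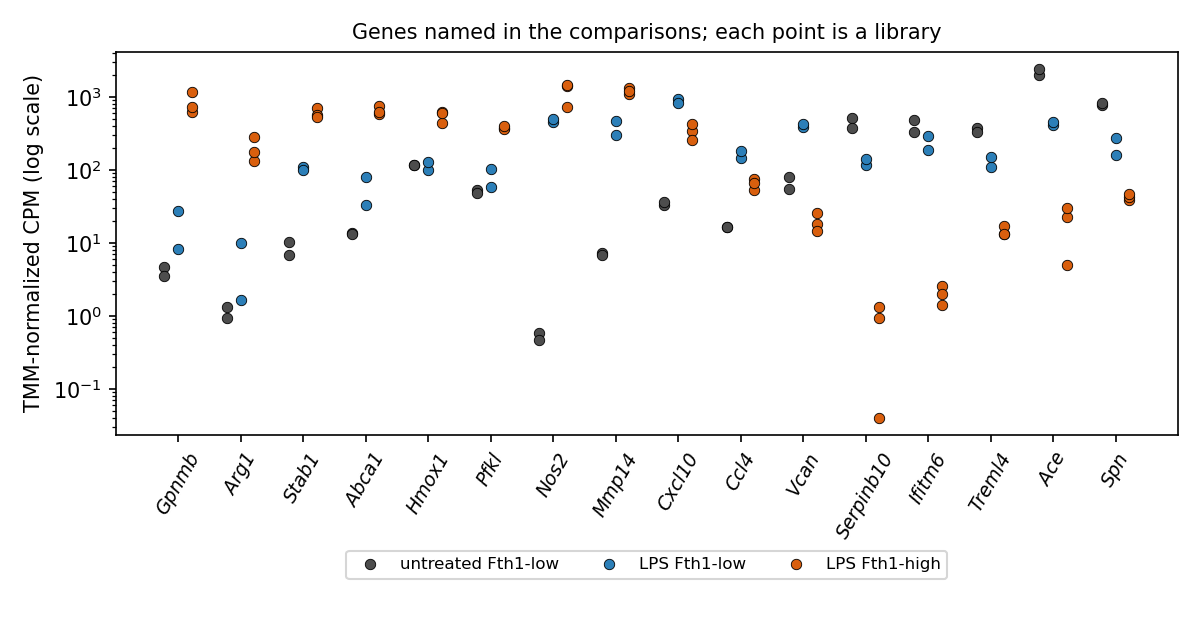
TMM-normalized CPM on a log axis for 16 genes, each point a library of untreated Fth1-low (n = 2), LPS Fth1-low (n = 2) or LPS Fth1-high cells (n = 3). Nos2 averaged 0.525, 481 and 1195 CPM in that order and Ace 2196, 437 and 19.4 CPM, whereas Cxcl10 (34.8, 882 and 340.5) and Vcan (67.6, 406 and 19.7) were highest in LPS Fth1-low cells.

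The order of the 3 groups was compared gene by gene, over genes already chosen for a gap between the outer 2. Of the 3315 genes called between LPS Fth1-high and untreated cells, 2711 (81.8%) had their LPS Fth1-low mean between the other 2 means, as Stab1 did at 8.63, 104 and 599.6 CPM and Ace at 2196, 437 and 19.4 CPM. Of the genes called both for LPS within the low gate and for the gate after LPS, 132 rose in both, 52 fell in both, 30 rose and then fell, and 2 fell and then rose. Independent lists would give 15.1, 3.93, 18.7 and 3.17. The 2 comparisons share the LPS Fth1-low libraries with opposite signs. Unchanged groups simulated 20 times gave at most 0 genes in the same direction and 2 in opposite directions. At most 5 genes were called for LPS within the low gate in those simulations, so their overlap had to be small. It is therefore no yardstick for the overlap in the data. The log2 changes of all tested genes correlated at 0.0061 (covariance 0.0073) where those simulations gave -0.700 (covariance -0.355). With 1 LPS Fth1-low library in each comparison, a division added after these counts were seen, 47 rose in both, 80 fell in both, 22 rose and then fell and 1 fell and then rose with replicate 1 set against untreated cells (5.96, 10.4, 11.7 and 5.30 for independent lists, correlation 0.117). The other way round these were 103, 5, 16 and 0 (17.0, 0.573, 9.34 and 1.04, correlation 0.044). Part of the opposite pairs with both libraries in both comparisons may come from the shared group, since 1 library on each side is a weak division. The counts of genes rising in both, falling in both and rising then falling were 49, 17 and 46 without LPS Fth1-low replicate 2, when 93 fell and then rose. They were 84, 14 and 26 without its replicate 1, 71, 11 and 16 without untreated replicate 1 and 74, 7 and 17 without untreated replicate 2. Without LPS Fth1-high replicate 2 they were 89, 45 and 21, and without replicate 3 they were 87, 38 and 17. The count of genes that fell and then rose was 1 without untreated replicate 1 and 0 without untreated replicate 2, LPS Fth1-low replicate 1 or any LPS Fth1-high replicate. Among the genes highest in LPS Fth1-low cells were Cxcl10, Ccl4 (16.4, 165 and 65.1 CPM) and Vcan, which kept both calls with any 1 library left out. Most of the 30 genes that rose and then fell lost a call in at least 1 such fit. Cxcl9, for instance, lost its call between the LPS gates when any 1 LPS Fth1-high replicate was left out.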

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

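Settings with ribosomal RNA genes left out, sample quality weights and equal depth were chosen only after the results were seen. Fth1 stayed higher in LPS Fth1-high than in LPS Fth1-low cells under every setting, from 1.90 to 2.63 with 1 library left out. For LPS Fth1-high against LPS Fth1-low, all other settings kept the counts of genes within 1.5 times of 503 higher and 625 lower. With 1 library left out these ranged from 263 to 682 higher, 379 to 602 lower and 658 to 1061 in all. For LPS Fth1-low against untreated cells (409 higher, 86 lower, 495 in all), the DESeq2 Wald test gave 632, 192 and 824, sample quality weights gave 47 lower and 329 in all, and with 1 library left out the ranges were 179 to 386 higher, 11 to 249 lower and 197 to 531 in all. For LPS Fth1-high against untreated cells (1690, 1625 and 3315), thinning to equal depth gave 977, 979 and 1956, where 8079 genes were tested, and leaving 1 library out gave 955 to 2184, 948 to 2012 and 1918 to 4143. Thinning tested fewer genes, and the fits with 1 library left out held fewer libraries. Sample quality weights kept all 13665 genes, and they and the DESeq2 Wald test used all libraries. Why the counts moved was not tested. Fitting the replicate number as a block gave 165 lower genes for LPS Fth1-low against untreated. The samples share only a number, and differences between replicates 1 and 2 correlated at -0.180 for untreated with LPS Fth1-low, 0.328 for LPS Fth1-low with LPS Fth1-high and -0.521 for untreated with LPS Fth1-high over 5076 genes. Of 31 lists, 11, 16 and 5 had a median that changed sign with 1 library left out, for LPS Fth1-high against LPS Fth1-low, LPS Fth1-low against untreated and LPS Fth1-high against untreated. Without untreated replicate 1 LPS Fth1-high against untreated cells turned from -2.13 to 1.95 for lung epithelial, -0.49 to 2.47 for fibroblast and -0.56 to 1.14 for alveolar macrophage markers. B cell markers turned from -0.91 to 0.89 between the LPS gates without LPS Fth1-low replicate 1. Values whose tested direction turned, with the test passed in at least 1 of the 2 fits, were the lung epithelial list median in LPS Fth1-low against untreated cells (-0.88; -3.56 without LPS Fth1-low replicate 2 to 2.57 without untreated replicate 1), the lysosome list median there (-0.05; -0.52 without LPS Fth1-low replicate 2 to 0.28 without its replicate 1), and Cyp2f2, a club cell gene, in LPS Fth1-high against untreated cells (-3.43; -4.34 without untreated replicate 2 to 0.39 without replicate 1). The cause was not tested. An estimated correlation in camera left no list call in any comparison. The depth of LPS Fth1-low replicate 1 limits genes below 5.02 CPM in that group, where 3 counts or fewer were expected.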

Other observations

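The tests of a wrong label, of a factor shared by replicate 1 libraries and of a mixture of cells were chosen only after the results were seen, as were the gene families below, and the test of low depth was written before. Complement genes were also counted as a family. Of 22 tested, 10 were higher and 1 lower in LPS Fth1-high than in LPS Fth1-low cells (12 and 1 adjusted over the family alone), 4 of the 10, C1qa, C1qb, C1qc and C3ar1, being on the macrophage differentiation list, with 6 higher when LPS Fth1-low replicate 1 or LPS Fth1-high replicate 2 was left out. Cfb, factor B of the alternative pathway, averaged 65.3, 1306 and 7123 CPM in untreated, LPS Fth1-low and LPS Fth1-high cells (adjusted p = 0.0050 between the LPS gates and 6.1e-04 for LPS within the low gate, edgeR). C1ra, a protease of the C1 complex, averaged 17.0 and 176 CPM in the LPS low and high gates (3.03 ± 0.38, adjusted p = 0.0015). Without LPS Fth1-low replicate 2 the log2 differences between the LPS gates were 3.04 for Cfb and 4.72 for C1ra, and Cfb rose by 3.71 with LPS in the low gate. C4b, of the classical pathway, rose with LPS in the low gate from 2.98 to 98.4 CPM (adjusted p = 2.1e-04) and stood at 75.8 CPM in LPS Fth1-high cells.

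Some receptors that guide cells between blood and tissue were called from untreated to LPS Fth1-high cells, with 4 of 17 chemokine receptors higher and 2 lower (4 and 4 adjusted over the family alone), 1 of 5 sphingosine 1-phosphate receptors higher and 2 lower (1 and 2), and 3 of 26 integrins higher and 8 lower (4 and 9, with 5 higher without LPS Fth1-low replicate 1). Over all 13665 genes tested, 1690 were higher and 1625 lower in that comparison, so calls were common in any set of genes. Whether these families exceeded that share was not tested. Between the LPS gates 1 and 1, 1 and 2, and 1 and 4 were called (2 and 2, 1 and 2, and 3 and 5 over each family alone), against 1 and 2, 1 and 1, and 0 and 2 without LPS Fth1-low replicate 1, 2 and 1, 1 and 0, and 2 and 1 without its replicate 2, no rise in chemokine receptors or integrins and 2 integrins lower without LPS Fth1-high replicate 2, and no integrin without its replicate 3. Ccr2, the receptor by which monocytes leave the marrow, averaged 1321, 1220 and 226 CPM in untreated, LPS Fth1-low and LPS Fth1-high cells (-2.44 ± 0.39 between the LPS gates, adjusted p = 0.0057, edgeR), and Cx3cr1, the fractalkine receptor of nonclassical monocytes, was 2.60 lower on the log2 scale in LPS Fth1-high than in untreated cells (adjusted p = 3.3e-04). S1pr5, a sphingosine 1-phosphate receptor of circulating nonclassical monocytes, averaged 86.7, 9.92 and 0.688 CPM (adjusted p = 5.7e-06 for LPS Fth1-high against untreated), and S1pr2, which restrains migration, averaged 29.2, 36.4 and 102 CPM (adjusted p = 0.0070 between the LPS gates). Among integrins, Itgal fell by 1.75 and Itga4 by 1.59 on the log2 scale between untreated and LPS Fth1-high cells (adjusted p = 0.0011 and 0.0013), while Itga5, the fibronectin receptor chain, rose by 2.03 (adjusted p = 0.0014). Ccr2 is also on the classical monocyte list, and Cx3cr1 and Itgal are on the nonclassical one, so their falls were already counted there.

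LPS Fth1-low replicate 1 differed from replicate 2 more than other replicates differed. Thinned to equal depth 20 times, the pair correlated at 0.924 on average where the lowest other pair had 0.954, and at 0.924 against 0.951 with ribosomal RNA left out before totals were matched (a test added after the first was seen), so low depth alone did not account for the gap. On a scale from untreated (0) to LPS Fth1-high (1) over 340 genes, replicate 1 lay at 0.455 and replicate 2 at 0.474, which does not place replicate 1 in another group. Differences between replicates 1 and 2 correlated at -0.180 between the untreated and LPS Fth1-low groups, the opposite sign to that of a technical factor shared by all 3 replicate 1 libraries, but at 0.328 between the 2 LPS groups, whose replicates 1 also held 19.4% and 8.42% ribosomal RNA. A factor shared by those 2 libraries and a makeup or quality particular to LPS Fth1-low replicate 1 remained open, and no biological explanation was tested.

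For 2711 of 3315 genes called between LPS Fth1-high and untreated cells, and so chosen for a gap between these 2, the LPS Fth1-low mean lay between theirs. A mixture of untreated Fth1-low and LPS Fth1-high cells in a single proportion would leave few genes highest in the middle group. Simulating it 20 times, with all 7 libraries only, gave at most 9 genes lowest in the middle group, where the data held 2. That direction therefore does not argue against a mixture. Genes highest in the middle group numbered 2.20 on average and 6 at most in the simulations. The data held 30, with 16 and 17 without untreated replicate 1 or 2, 26 and 46 without LPS Fth1-low replicate 1 or 2, 28, 21 and 17 without LPS Fth1-high replicate 1, 2 or 3, and 22 or 16 with 1 LPS Fth1-low library in each comparison (a division added after the result was seen), so a mixture of that kind could not be the whole cause. Mmp25, a membrane-anchored metalloprotease, at 1.17, 20.6 and 3.42 CPM, and Lrg1, a secreted glycoprotein, at 1.87, 54.5 and 3.12 CPM, were among the genes highest in the middle group. So was Il1r2 of the neutrophil list. That list's median log2 CPM was 2.02 and 1.63 untreated, 3.82 and 4.50 in LPS Fth1-low and 2.24, 2.53 and 2.75 in LPS Fth1-high libraries. Its sum, however, was highest in LPS Fth1-high replicate 2 at 1429.5 CPM. Whether other cell types added to these genes was not tested. Whether each LPS Fth1-low cell held an intermediate state was not tested, since the libraries average many cells.

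Single values belonged to no comparison. Sftpc was 494 CPM in untreated replicate 1 and 1.40 in replicate 2. Xist, transcribed in females, and Ddx3y, of the Y chromosome, were 3.58 and 97.9 CPM in untreated replicate 1, 274 and 0.186 in replicate 2, 72.0 and 68.6 in LPS Fth1-low replicate 1, 176 and 37.2 in its replicate 2, 34.8 and 78.3 in LPS Fth1-high replicate 1, 1.95 and 68.8 in replicate 2, and 363 and 1.66 in replicate 3. Both LPS Fth1-low libraries and LPS Fth1-high replicate 1 thus held RNA of both sexes, and how it came there was not tested. Untreated replicates 1 and 2 differed in the sex these transcripts mark, as did LPS Fth1-high replicates 2 and 3. That argues against repeated preparations of the same mice for these pairs, and sex adds to the spread between them. Col1a1, the collagen of fibroblasts, was 80.4 CPM in LPS Fth1-low replicate 1 and 6.58 in replicate 2.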
